A study of Mus musculus with 4 samples.

How the data were processed

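Gene expression was measured in hearts of outbred ICR mice that had received, at postnatal day 1, an injection of a viral vector carrying Tbx6 or of phosphate-buffered saline (PBS). Hearts were taken 7 or 30 days after the injection, and 1 array was deposited for each of the 4 combinations of injection and day. The labels place the injection under the skin of the back, while other label fields speak of introduction into the heart. How many hearts went into each RNA sample, the litter and the sex of the animals are not given in the sources used here. The control was PBS and not a vector without Tbx6, so every difference between injections holds the vector as well as the gene.

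Per the labels, total RNA was amplified and biotin-labelled as single-stranded cDNA with a whole-transcript kit and hybridised to mouse Clariom S arrays, which carry 1 colour. Per the labels and the submitters' processing notes, the deposited values were made with the SST-RMA algorithm in Affymetrix Expression Console 1.4 and are taken as log2 expression values. The log base is not written in the labels, and base 2 was taken from the range of the values and from the usual output of RMA. The highest deposited value was 19.9 on the log2 scale, and 7 genes reached it on at least 1 array. Of these, Atp2a2, Fabp3 and Tpm1 stood at it on every array, so differences of such abundant heart genes were compressed. Arrays have no read depth, and their number limits the precision.

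The value table held 28846 probe sets. Names came from the platform annotation given with the series, in which 19572 probe sets carried 1 gene symbol and 0 carried several. A further 2634 transcript probe sets are unnamed here, and 6640 were control probe sets. The Entrez identifiers of all 19572 named probe sets were found with the same symbol in a RefSeq gene table (assembly GRCm38.p6), which was used only for names, for chromosomes and for the order of neighbouring genes. Where a gene had more than 1 probe set (55 genes), the probe set with the highest mean over the 4 arrays was kept, which left 19505 genes. All 4 columns of values were used.

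Differences were taken between single arrays on the log2 scale as deposited, without further normalisation. Counts of genes were made among the 9753 genes whose mean over the 4 arrays was at or above the median of all genes (5.30 on the log2 scale), with a size rule of 1.5-fold. A reading at or below the highest background probe set of its array is called at background. A difference with 1 such reading is given as a bound, at least the difference left after raising that reading to the highest background probe set, and none is given where both readings are at background. This was added after the values had been seen and leaves the counts and the test as they were. The 4 differences between single arrays have no replicate check and no p-value. The only replication lies across the other factor, so an additive model with injection and day as terms was fitted to all 4 arrays with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment over the 9753 genes and a threshold of 0.05. This model leaves 1 residual degree of freedom, which holds the spread between hearts together with any injection effect that differs between days. Its p-values and standard errors (SE) therefore rest on a variance borrowed almost entirely from other genes. An SE given here is not the measured spread of that gene. The words rose and fell are used only for genes past this test. Correlations across genes were computed with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.

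Before the data were examined, 37 gene lists for heart function, the cell cycle, metabolism, stress and the cell types in and around the heart were fixed. For each list the median difference of its measured members was placed among 10000 random lists of the same size matched on mean expression in 20 bins. A list outside the central 95% of these is described as outside the matched range. This describes the arrays and is not a p-value, since genes of a list vary together and random genes do not. The rule for naming genes was also fixed then. It took Tbx6, the 10 highest and 10 lowest genes of each difference, the 10 genes per direction with the largest differences repeated on both days, the 10 largest tested changes per direction, and up to 4 members per list. Predicted genes and near-identical copies could be passed over. The tests of explanations name further genes outside this rule, from lists written after the data were seen.

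The limma step was tested on simulated data in which 100 genes changed by 1 and 100 genes by 2 log2 units between injections, equally on both days, among the 9753 genes. It recovered 70% of the former and 100% of the latter, with 17 unchanged genes called. The simulated noise was Gaussian and used gene variances that limma had already drawn toward each other, so these shares may be too favourable. The list step placed a simulated list shifted by 1 log2 unit outside the matched range and an unshifted list inside it.

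The alternatives tried were quantile normalisation, centring of each array on its median, no expression filter, a filter at the 75th percentile, a 2-fold size rule, averaging of a gene's probe sets, an intensity trend in eBayes and a model without the other factor. For the lists they were the mean in place of the median, unmatched random lists and members above the median expression. Leaving out genes on the X and Y chromosomes, leaving out the genes of lung, airway and fat lists, and keeping only genes above background on all 4 arrays were chosen after seeing the data. Unnamed and control probe sets were left out of all comparisons between groups.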

Results

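Tbx6 is a T-box transcription factor of the presomitic mesoderm, and the series asked how the heart's expression profile differed after a vector carrying it had been given to newborn mice. The data were 4 Clariom S arrays of heart RNA, 1 each for PBS and Tbx6 at day 7 and for PBS and Tbx6 at day 30 after injection. There were no replicates within a group, so differences between single arrays are given as sizes without a test. The median log2 value over all genes was 5.33 after PBS and 5.34 after Tbx6 at day 7, and slightly lower on both arrays of day 30. Over the 9753 filtered genes, Pearson correlations across genes were 0.985 for the pair at day 7, 0.989 for the pair at day 30 and 0.936 to 0.941 between arrays of different days.

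The Tbx6 probe set read 3.70 after PBS and 4.14 after Tbx6 at day 7, and 3.57 and 3.66 at day 30, on the log2 scale. The differences of 0.44 and 0.09 were below 1.5-fold, and every reading was below the median of all genes and within the range of the array's background probe sets, whose mean was 4.02 to 4.09 and whose highest values were 5.77 to 6.05. Which part of the transcript the vector carried, and whether the probes cover it, are not given in the sources used here. The probe set therefore does not check the labels, and the groups are named as the labels give them.

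**Figure D1:**
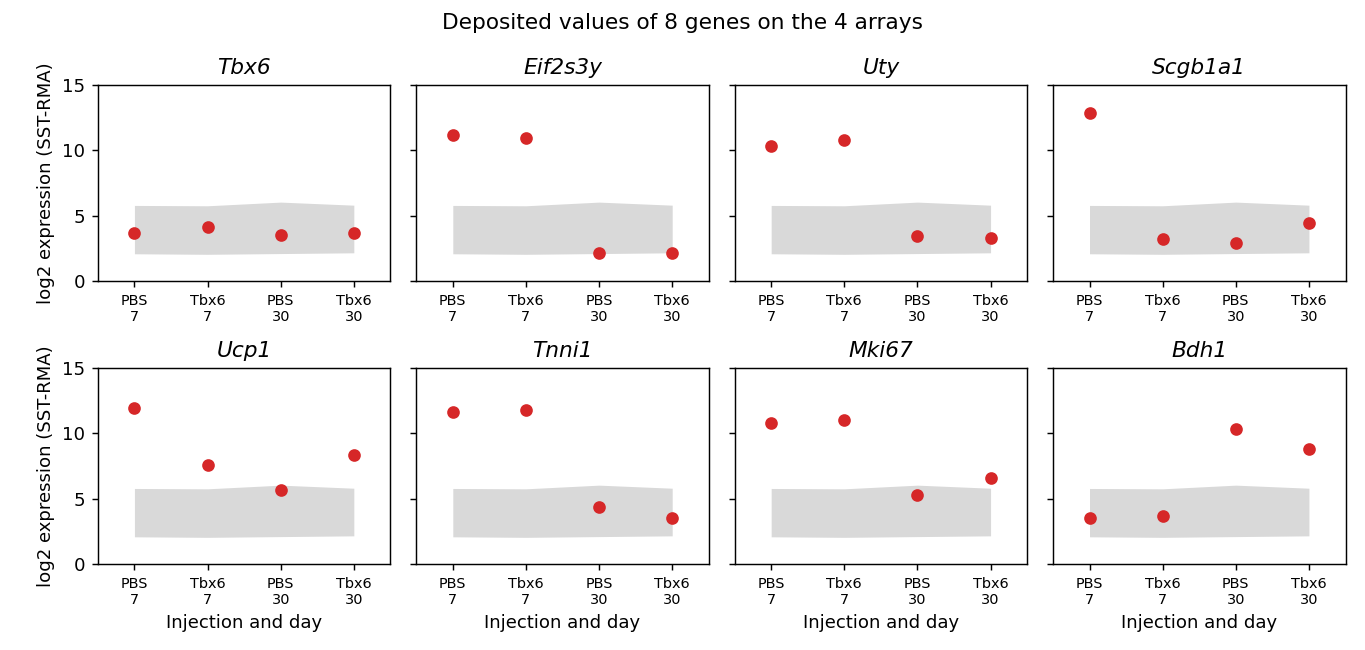
Deposited log2 values (vertical axis) of 8 genes on the 4 arrays (horizontal axis, injection and day), 1 point per array, with the range of the background probe sets shaded. Tbx6 lies within the background on all 4 arrays, Eif2s3y and Uty are above 10 at day 7 and among the background at day 30, and Scgb1a1 is above the background on the PBS array of day 7 alone.

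The first comparison set Tbx6 against PBS at day 7. The lowest differences at day 7 included genes known from the airway lining, of which Scgb1a1 and Scgb3a1 were above background on the PBS array of day 7 alone. The lung epithelial list as a whole was inside the matched range. Scgb1a1, the club cell secretory protein, read 12.89 after PBS and was at background after Tbx6, a log2 difference of at least -7.12. It was at least -5.03 for Scgb3a1, -4.30 for Cbr2 and at least -2.40 for the club cell cytochrome Cyp2f2. Of these, Cbr2 was also high at day 30, at 12.32 after PBS and 12.11 after Tbx6. Ucp1, the uncoupling protein of brown fat, differed by -4.32, Egr1, an immediate-early transcription factor, by -2.66, Tmem128 by at least -1.26 and Car3, a carbonic anhydrase abundant in fat and muscle, by -2.22. The spliceosome factor Cwc22, whose copy number varies between mice, read 13.81 after PBS and was at background after Tbx6, a difference of at least -8.04. The highest differences were in Scd4 (3.81), a stearoyl-CoA desaturase, Baiap2l1 (3.80), an adaptor that shapes membranes with actin, Mid1 (3.39), a microtubule-associated ubiquitin ligase, Retsat (2.41), a retinol saturase, and Haus8 (2.39), a spindle protein. Ppdpf (2.19), the efflux pump Abcb1a (2.06), Adam22 (2.01), Hamp (1.97), which encodes the iron hormone hepcidin, and Aldh1b1 (1.89), an aldehyde dehydrogenase, followed. Baiap2l1, Abcb1a and Hamp were low on the PBS array of day 7 alone (7.54, 7.98 and 11.11). On the PBS array of day 30 they read 11.98, 9.91 and 13.15, near the Tbx6 array of day 7 or above it. For the other genes of this group the Tbx6 array of day 7 was the highest.

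Of the 37 lists, 9 lay outside the matched range at day 7, where 1.85 would be outside by the range's definition. Genes of DNA replication were lower after Tbx6, with a median of -0.34 over 31 members, of which 1 was at least 1.5-fold higher and 7 lower. Among them Cdc45 differed by at least -0.82 and Mcm2 by -0.74, while 10 members, Gins1 and Gins2 included, were at background on both arrays. The mitosis list had a median of -0.04 and was inside the range. Fatty acid oxidation genes were higher, with a median of 0.23 over 29 members, 6 at least 1.5-fold higher and 0 lower, led by Acot1 (1.10), Acot2 (0.79), Ucp3 (0.76) and Mlycd (0.74). Oxidative phosphorylation genes had a median of 0.16 over 35 members, with Ndufb8 at 0.72 and Sdha at -0.68. Heat shock genes had a median of 0.26 over 11 members, with Hspe1 at 0.72 and Hsph1 at 0.57 or more.

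Lists with lower medians at day 7 were those of macrophages, interferon response, matrix, immediate-early response and adipocytes. Antigen presentation (median -0.13, with 0 higher and 4 lower) and lymphocytes (-0.12) were inside the range. In these 7 of 15 and 16 of 17 members were at background on both arrays, so their medians measure little. The macrophage and myeloid list had a median of -0.29 over 28 members, with 1 higher and 5 lower. Of the 28, 13 were at background on both arrays. Over the 20 members past the expression filter the median was -0.31, also outside the range. The lower ones included the neutrophil protein genes S100a8 (at least -0.33) and S100a9 (at least -0.48) and the complement gene C1qa (at least -0.47), against Fcer1g (1.06). Interferon-stimulated genes had a median of -0.25 over 30 members, of which 18 were at background on both arrays, with Gbp3 at -1.02 or below and, on the other side, a higher Xaf1. Fibroblast and matrix genes had a median of -0.17 over 32 members, 1 higher and 5 lower, with Ccn2 at -1.41, Tnc, which encodes tenascin C, at -1.03. Immediate-early genes had a median of -0.33 over 21 members, 2 higher and 6 lower, with Ccn1 at -1.70 and Myc at -1.67 beside Egr1. Of the 21, 9 were at background on both arrays. Adipocyte genes had a median of -0.33 over 11 members, 0 higher and 4 lower, with Adipoq at -1.91 after Ucp1. Igtp, Dlk1, Fosb and Plin1, which the naming rule also takes, were at background on both arrays. All of these lists were compared with the same PBS array, on which Scgb1a1, Scgb3a1 and Ucp1 were also high.

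In all, 1525 of the 9753 genes differed by at least 1.5-fold at day 7, 705 higher and 820 lower after Tbx6, and 276 differed by at least 2-fold. In 313 of the 1525 at least 1 reading was at background, and in 62 both were. With 1 array on each side these counts hold differences between the hearts sampled as well as any effect of the injection.

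The same comparison at day 30 gave a different set of genes at the top. Fat genes were higher after Tbx6, with Adipoq, which encodes the fat hormone adiponectin, at 2.33. Ucp1 and the lipid droplet gene Cidec were at background after PBS and higher by at least 2.29 and 1.83 after Tbx6. Pdk4, the kinase that shuts off pyruvate dehydrogenase when fat is burned, read 10.14 after PBS and 12.37 after Tbx6. Ighmbp2 (at least 0.42), Eif4a3 (1.78), Defb15 (at least 1.18), the platelet tubulin gene Tubb1 (1.64), Ivd (1.62), an enzyme of leucine breakdown, and the desaturase gene Scd1 (1.58) completed the highest differences. The lowest were Fggy (at least -1.47), a carbohydrate kinase, Cdk11b (-1.83), Memo1 (-1.81), Ttc39c (at least -0.43), Nppb (-1.67), which encodes the B-type natriuretic peptide of stretched heart muscle, Cyfip2 (-1.63), a regulator of actin, Casq1 (-1.58), a calcium store protein, Ccdc69 (at least -0.61), Fam114a2 (at least -1.21) and Bdh1 (-1.53), an enzyme of ketone body metabolism. Their order is that of the deposited values, in which readings at background count as they stand.

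At day 30, 11 of the 37 lists lay outside the matched range. The adipocyte list had a median of 0.65 over 11 members, 7 at least 1.5-fold higher and 0 lower. Fatty acid oxidation genes had a median of 0.18 over 29 members, 5 higher and 0 lower, with the uncoupling protein gene Ucp3 at 0.79, Acot2 at 0.75 and Acads at 0.68 after Pdk4. Macrophage and myeloid genes were higher, with a median of 0.25 over 28 members, 7 higher and 0 lower. Fcgr1 was at 0.54 or more, while 9 members, Ccl8 included, were at background on both arrays. Antigen presentation genes had a median of 0.40 over 15 members, of which 6 were at background on both arrays. The histocompatibility genes H2-D1 and H2-Aa differed by 1.37 and 1.30, and Tapbp by -0.84. Fibroblast and matrix genes had a median of 0.18 over 32 members, 6 higher and 2 lower, with Fbln2 at 1.21 and Ddr2 at -0.91. Mesothelial and epicardial genes had a median of 0.36 over 12 members, but 7 of these, among them Krt8 and Upk1b with the largest differences, were at background on both arrays. Atrial genes had a median of 0.25 over 13 members, with Stard10 at 0.73, Clu at 0.63, the atrial light chain gene Myl7 at 0.61 and, on the other side, Bmp10 at -0.59. These lists were higher on the same array as the fat genes.

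Lists with medians below the matched range at day 30 were glycolysis, ribosomal proteins, mitosis and early mesoderm. Glycolysis genes had a median of -0.19 over 20 members, with the hexokinase gene Hk1 at -0.52 and with Slc16a3 at background on both arrays. Ribosomal protein genes had a median of -0.22 over 16 members, led by Rps18 (-0.62). The mitosis list had a median of -0.25 over 41 members, but 35 of these, among them Bub1b and Spc25 with the largest differences, were at background on both arrays, so the median measures no lowering. Of the others, picked out after their values were seen, Mki67 (at least 0.55), Kif23 (0.56) and Cenpa (0.49) were higher, Cenpe (-0.43) was lower, Top2a (-0.03) hardly differed and Ccnb2 had no bound left. Over the 18 members that passed the expression filter the median was -0.05, inside the range. Early mesoderm genes, the group in which Tbx6 acts in the embryo, had a median of -0.36 over 16 members, but 13 of these, among them Mesp1 and Foxc2, were at background on both arrays, so no direction can be given for the list. The 3 others differed by -0.69 (Lfng), -0.40 (Foxc1) and 0.67 (Meox2). Only 5 members passed the expression filter, and over these the median was -0.13, inside the range. At day 7 this list had a median of -0.01 and was inside the range.

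At least 1.5-fold differences at day 30 numbered 1286, of which 695 were higher and 591 lower, and 209 genes differed by at least 2-fold. In 354 of the 1286 at least 1 reading was at background, and in 107 both were. Of the 37 lists, 21 were inside the matched range on both days. They were Tbx6 itself, cardiac transcription factors, cell cycle inhibitors, mature cardiomyocyte, fetal cardiac, ion channel, endothelial, smooth muscle, lymphocyte, thymocyte, erythroid, fast skeletal muscle, lung epithelial, liver, neuronal, endoplasmic reticulum stress, hypoxia, clock, sex-linked, growth factor and Hippo-YAP genes. The lung list held Scgb1a1, but at day 7 its 7 other members were at background on both arrays and its median was 0.05. The same held on both days for 16 of 17 lymphocyte, 15 of 16 fast skeletal muscle and 9 of 10 liver members. It also held for 8 of 9 neuronal and 8 of 10 erythroid members. Being inside the range says little for such lists. The mature cardiomyocyte list held genes with equal readings on every array, such as Actc1 and Pln, which pull its median toward no difference. Some lists outside the range came inside it under an alternative setting. At day 7 these were matrix genes (median -0.14 after quantile normalisation), adipocyte genes (-0.20 over members past the filter) and heat shock genes (mean 0.19). At day 30, beside mitosis and mesoderm, they were glycolysis (mean -0.16), mesothelial genes (mean 0.24) and atrial genes (against unmatched random lists).

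The day 7 and day 30 differences between injections share no array, so their agreement was examined next. Genes higher after Tbx6 on both days included the aldo-keto reductase gene Akr1b8 (1.07 and 1.09), Mthfsl (1.05 and 0.96), Mid1 (3.39 and 0.94), the gluconeogenic enzyme gene Fbp2 (1.21 and 0.93), Rmi1 (0.95 and 0.89), and the matrix gene Efemp1 (higher at day 7, and 0.88 at day 30). Lower on both days were Zzz3 (-0.98 and -0.92) and Cdk11b (-0.85 and -1.83), and, with both readings after Tbx6 at background, Cstf2t (at least -0.64 and -0.71) and the ATP-gated channel gene P2rx4 (at least -0.26 and -0.53). With a day 7 reading at background, Tsen15 (at least -0.83, and -0.84 at day 30) and Hsd17b7 (at least -0.31, and -0.99 at day 30) were also lower, and Zranb3, at background after PBS, was higher by at least 0.19 and 0.50. Gpn3 was higher by at least 0.28 at day 7, with no bound left at day 30. For some genes that the deposited values place on both days, both readings of 1 day were at background, so no repeat was measured. These were the glutathione transferase gene Gsta3 (1.47 at day 30), Klf15 (0.87 at day 30), a transcription factor of fasting metabolism, Cyfip2 (-1.63 at day 30), Tmem150c (-1.04 at day 30) and Cwc22, with its difference at day 7 alone. Fatty acid oxidation was the 1 list outside the matched range in the same direction on both days. The adipocyte, macrophage and matrix lists were outside it in opposite directions. With 9 and 11 of the 37 lists outside the range, 1 list with a shared direction could also arise between unrelated days. It does not by itself show a repeat.

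Across all 9753 genes the differences between injections at day 7 and day 30 had a Pearson correlation of -0.0384 and a Spearman correlation of -0.0267, where genes are not independent replicates. Of the genes with at least 1.5-fold differences on both days, 138 had the same direction (73 higher, 65 lower) and 152 opposite directions, against 99.9 and 101 for independent lists of those sizes. Among the 7884 of these genes that were above background on all 4 arrays, a setting chosen after seeing the data, the counts were 91 and 91. By limma's additive model, 0 genes passed the adjusted threshold for injection, and 421 had an unadjusted p under 0.05. The same model fitted to crossed pairs, in which Tbx6 at day 7 and PBS at day 30 were set against the other arrays, had 445 such genes. In the 36 lists with tested genes 0 genes passed for injection, also when adjusted over the list alone, where the lymphocyte, fast skeletal muscle and liver lists had 1 tested gene each and the Tbx6 list had 0. The lowest unadjusted p, 0.000185, was that of Cyfip2 (log2 change -1.54, SE 0.24, Benjamini-Hochberg adjusted p of 1 by limma), whose day 7 readings were at background.

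**Figure D2:**
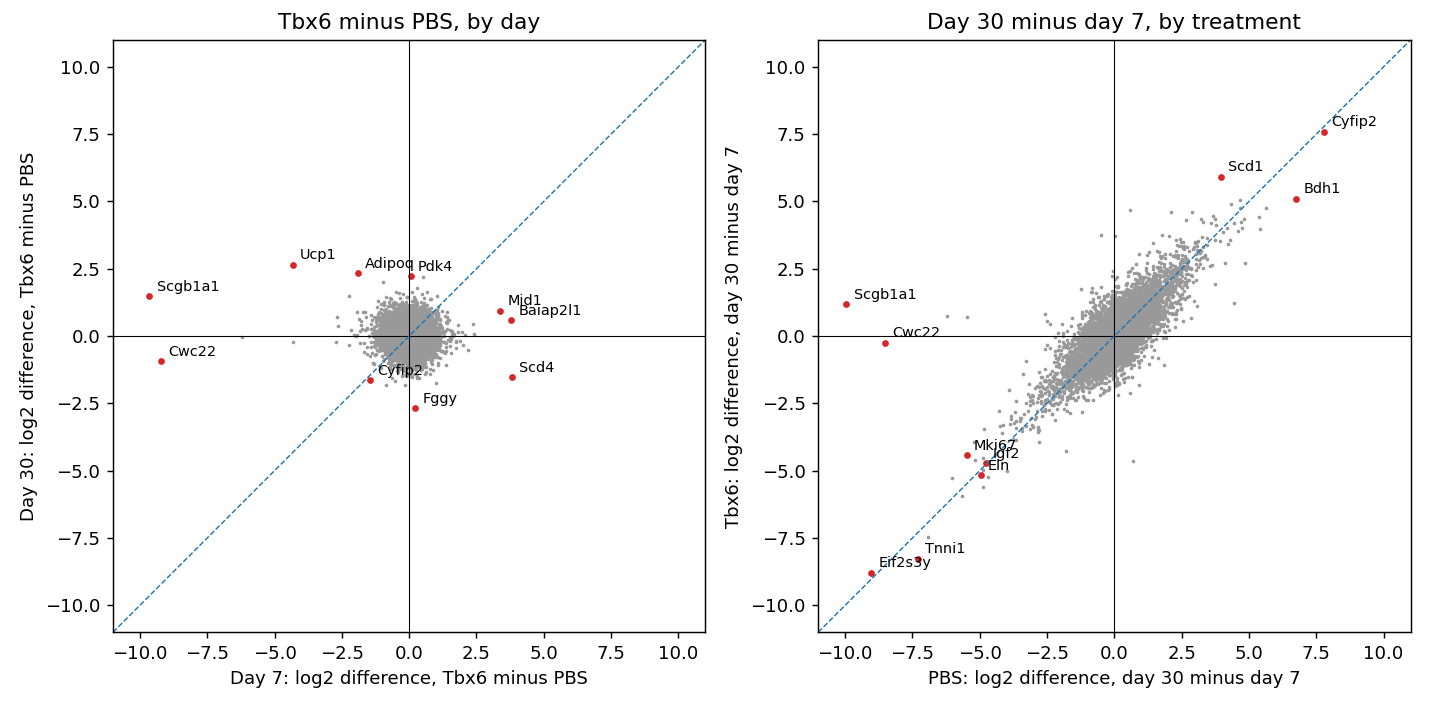
Left, log2 difference between Tbx6 and PBS at day 7 (horizontal) against that at day 30 (vertical); right, log2 difference between day 30 and day 7 after PBS (horizontal) against that after Tbx6 (vertical). Each point is 1 of the 9753 filtered genes, named genes are red and the dashed line marks equality. The left cloud has no trend (correlation -0.0384) and the right cloud follows the line (correlation 0.786).

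The comparison of days asked how the heart changed between 7 and 30 days after injection, with both injections as the pair of observations. All tested genes of mitosis fell, and more tested genes of glycolysis rose than fell. Mki67, the proliferation marker, fell by at least 4.58 on the log2 scale, cyclin A2 (Ccna2) fell by at least 2.72 and Ube2c, of the anaphase machinery, fell by at least 1.82, each with readings at background at day 30. Tnni1, the slow skeletal troponin I of the fetal heart, was at background on both arrays of day 30 and fell by at least 5.79 (Benjamini-Hochberg adjusted p of 5.01e-06 by limma on the deposited values). The elastic fibre genes Mfap2 and Eln fell by 5.65 (SE 0.27) and 5.06 (SE 0.24), the potassium channel subunit gene Kcne1 fell by 4.97 (SE 0.26), and the imprinted growth genes Mest and Igf2 fell by 4.92 (SE 0.24) and 4.76 (SE 0.24). The histone gene H2ac15, which has near-identical copies and is uncertain, fell by at least 5.22. A probe set annotated to Mir675, a microRNA gene, fell by 5.79.

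Among the genes that rose were Scd1 (4.94, SE 0.42), Ptgds (4.87, SE 0.25), which encodes prostaglandin D synthase, Gstk1 (4.69, SE 0.35) and the transcription factor gene Zbtb16 (4.59, SE 0.25). Cyfip2, Bdh1, Plaat1 and the clock gene Ciart were at background on both arrays of day 7, and the rise was at least 6.77 for Cyfip2, 3.77 for Bdh1 and 2.47 for Plaat1. Predicted genes were passed over. In total 2562 genes passed limma's adjusted threshold, of which 1385 rose and 1177 fell. Of them 156 had both day 7 readings at background, 186 had both day 30 readings there and 5 had all 4 there, and the size of such changes is not measured. Without genes on the X and Y chromosomes 2465 passed, a setting chosen after seeing the data.

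The arrays of day 7 and day 30 also differed in Y-linked expression, which marks RNA from males. The Y-linked genes Eif2s3y (11.18 and 10.96 at day 7, 2.15 and 2.16 at day 30), Uty (10.34 and 10.76, then 3.43 and 3.28) and Kdm5d (6.12 and 5.93, then 2.60 and 2.65) were read above background at day 7 only. Every day difference given here is therefore also a difference between arrays with and without Y-linked expression.

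All 18 tested genes of mitosis and cytokinesis fell, as did 14 of 19 of DNA replication, and 0 rose in either list. In the latter, Prim1, of the primase, fell by at least 1.83, the replication helicase gene Mcm2 fell by at least 1.61 and Rrm2, of nucleotide synthesis, fell by at least 0.95, each with readings at background at day 30. The counts were the same when adjusted over the list alone. Of 28 tested fibroblast and matrix genes 18 fell and 0 rose (18 fell and 1 rose adjusted over the list alone), among them Postn, a matrix gene of growing and injured hearts (-4.57, SE 0.33), and Col1a1, the collagen I gene (-3.57, SE 0.27). In the growth factor list 9 of 17 fell and 1 rose (9 and 2 adjusted over the list alone). The imprinted genes Plagl1 (-3.20, SE 0.25) and Peg3 (-3.04, SE 0.32) followed Mest and Igf2, and Igf2 belongs to both lists. Of 19 endothelial genes 7 fell and 1 rose (9 and 1 adjusted over the list alone), where Flt1 rose (1.94, SE 0.24) and Aplnr fell (-1.47, SE 0.27), and of 16 ribosomal protein genes 5 fell and 0 rose, with the same counts adjusted over the list alone.

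In each list of energy metabolism more genes rose than fell. Of 18 tested glycolysis genes 11 rose and 1 fell (13 and 1 adjusted over the list alone), with the insulin-responsive glucose transporter gene Slc2a4 at 3.06 (SE 0.25), Hk2 at 2.53 (SE 0.24) and Slc2a1 at 2.39 (SE 0.24). Of 35 oxidative phosphorylation genes 13 rose and 0 fell, also when adjusted over the list alone, led by the muscle cytochrome oxidase subunit gene Cox7a1 (3.14, SE 0.25). Of 29 fatty acid oxidation genes 10 rose and 4 fell (10 and 5 adjusted over the list alone). The largest changes were those of Lpl (2.24, SE 0.25), Cpt2 (2.12, SE 0.24), Ppara (1.62, SE 0.24) and, falling, Angptl4 (at least -1.49). For heat shock genes 5 of 11 rose and 0 fell, also when adjusted over the list alone.

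Some of the most abundant contractile genes stood at the highest value the arrays gave, where a change cannot be read. Of 28 mature cardiomyocyte genes 4 rose and 0 fell, also when adjusted over the list alone, and they were Tcap, Ckmt2, S100a1 and Hrc. Of 16 fetal cardiac genes 8 fell and 2 rose, also when adjusted over the list alone. After Tnni1 the largest changes were those of the skeletal actin gene Acta1, which rose by 3.42 (SE 0.34), and of Kit (-1.59, SE 0.24) and Vim (-1.28, SE 0.24), which fell. Of 17 ion channel genes 6 rose and 4 fell (7 and 4 adjusted over the list alone), led after Kcne1 by Kcnip2, a subunit of the transient outward potassium channel, at 2.94 (SE 0.24).

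Immune genes were among those that rose between days. Of 20 tested macrophage and myeloid genes 14 rose and 0 fell (16 and 0 adjusted over the list alone), among them the complement genes C1qb (2.97, SE 0.27) and C1qc (at least 2.42), the chemokine gene Ccl9 (at least 2.85) and the lysozyme gene Lyz2 (2.55, SE 0.30). Of 16 interferon-stimulated genes 10 rose and 0 fell (13 and 0 adjusted over the list alone), among them Ifit3b (at least 2.05) and Ifit3 (at least 2.14). Of 10 antigen presentation genes 4 rose and 0 fell, also when adjusted over the list alone. Clock genes went both ways, 9 rising and 3 falling of 15, also when adjusted over the list alone. Dbp rose by 3.73 (SE 0.25) and Nr1d1 by 2.34 (SE 0.24), while Arntl, the activator of both, fell to background by at least 1.80. The hour at which hearts were taken is not given in the sources used here.

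**Figure D3:**
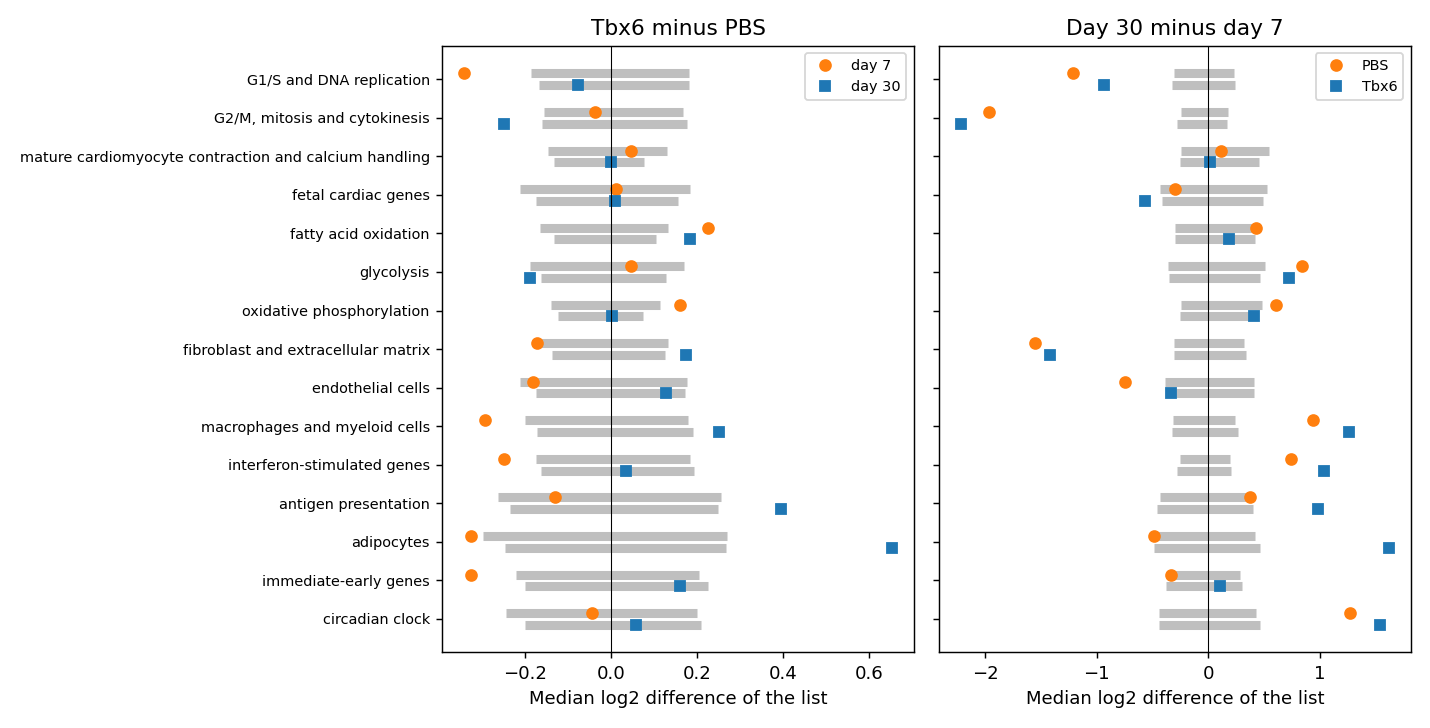
Median log2 difference (horizontal axis) of 15 gene lists (vertical axis) between injections, left, and between days, right; orange circles stand for day 7 or PBS and blue squares for day 30 or Tbx6. Grey bars span the central 95% of 10000 matched random lists. The mitosis list lies far below its bar in both day differences, at -1.97 and -2.22, and fatty acid oxidation lies above its bar in both differences between injections.

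The day differences were similar after both injections. Between day 7 and day 30, 4236 genes differed by at least 1.5-fold after PBS (2137 higher, 2099 lower) and 4301 after Tbx6 (2233 higher, 2068 lower). These pairs share no array, and across genes their differences had a Pearson correlation of 0.786 and a Spearman correlation of 0.710. Of the genes past the size rule in both, 2688 had the same direction and 83 opposite directions. The PBS pair alone held Scgb1a1 (at least -6.84), Cwc22 (at least -7.76), Ucp1 (at least -5.87) and Scgb3a1 (at least -4.75) among its 10 lowest genes, and the Tbx6 pair alone held Cbr2 (4.68) and the chemokine gene Ppbp (at least 3.95) among its 10 highest. The mean difference between injections had a correlation of 0.0694 across genes with the mean difference between days.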

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

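The tests for surfactant genes, for the mean of the airway markers, for lower airway genes at day 30 and for an equal effect on both days were chosen after the result was seen, and the others before.

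Differences between injections that pointed in opposite directions at day 7 and day 30 are listed here as the day 7 difference minus the day 30 difference. With 1 array per group this contrast was not tested. It was 5.32 for Scd4, -11.13 for Scgb1a1, -6.98 for Ucp1, -3.40 for Cyp2f2, -3.70 for Car3, -4.24 for Adipoq, -2.99 for Cidec and 2.73 for Ttc39c. These are differences of deposited values. Both day 30 readings of Scgb1a1 were at background, so its direction at day 30 was not measured, and for Ucp1, Cyp2f2, Cidec and Ttc39c 1 or more readings were at background, so the sizes are uncertain. For list medians it was -0.35 for fibroblast and matrix genes, -0.55 for macrophage and myeloid genes and -0.98 for adipocyte genes.

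Among 6546 mouse control probe sets, which no comparison used, 12 were at least 4-fold higher after Tbx6 on both days, while 24 were at least 4-fold lower on both days and 39 differed that much in opposite directions.

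The secretoglobin genes Scgb1a1 and Scgb3a1 read 12.89 and 10.80 on the PBS array of day 7 and were at background on the others, while Cbr2, also of the airway, was as high at day 30. Airway tissue carried over with the heart tissue of the PBS array of day 7 was tested with 34 airway markers whose values had not been looked at. Their median of 0.12 (percentile 94.0 of matched random lists) stayed short of the bound set beforehand. That test had little reach, since 28 of the 34 were no higher than the background on any array. The other 6 did not behave alike. Scgb3a2 read 9.65 on the PBS array of day 7 and was at background on the others. Bpifb1 was barely above background on that array alone, and Lypd2 on the Tbx6 array of day 30 alone. On the PBS array of day 7, Cyp4b1 (-1.30), Ces1d (-1.56) and Krt7 (-0.15) were lower than the mean of the others. Those include both arrays of day 30, where Cyp4b1 and Ces1d were higher after both injections. Against the Tbx6 array of day 7 alone the 3 genes hardly differed (Tbx6 minus PBS 0.02, 0.15 and -0.03). The mean of the same 34 genes was 0.34 (percentile 99.9), but the mean was taken up only after the median had missed its bound and these values were known, so a small amount of airway secretory cell RNA stays open as a candidate explanation and is not supported by an independent test. Surfactant genes were at background on all 4 arrays, so their median of 0.14 measures no difference and alveolar tissue was not seen but not excluded in small amounts, and for a lowering by Tbx6 the median at day 30 (0.24 over 12 airway genes) says little, since 3 of the 12 were above background after PBS; of these Cbr2, lower by -4.30 at day 7, differed by -0.22, Tppp3 by 0.71 and Aldh1a1 by 0.24, so Cbr2 was not lowered on both days and the secretoglobins stay open.

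The Y-linked genes Eif2s3y and Uty were high on both arrays of day 7, and both, with Kdm5d, were at background on both arrays of day 30. RNA from males was therefore present at day 7, though not shown to be all of it, and none was seen at day 30. If the day 7 RNA came from males alone and the day 30 RNA from females, X-linked genes that escape inactivation would be higher at day 30. The median over Kdm6a, Kdm5c, Eif2s3x and Ddx3x was higher by 1.10 after PBS and by 1.38 after Tbx6, as this predicts. These 4 were named beforehand. Over all 7 measured genes of the list the medians were 0.56 after PBS and 0.98 after Tbx6. Utp14a (0.06 and 0.48) and Pbdc1 (-0.02 and 0.55) hardly differed after PBS and were higher at day 30 after Tbx6. Mid1ip1, at background at day 7, was higher at day 30 by at least 2.67 after PBS and 2.87 after Tbx6. Kdm6a (1.93 and 1.78) and Eif2s3x (1.64 and 2.04) differed by more than 1 unit. How many units a second copy would add in these values was not checked, so the sizes do not tell whether it alone accounts for them. Whether sex adds to the other day differences cannot be told apart from age, since both change together on all 4 arrays. Genes on X and Y made up 3.79% of the genes called between days and 3.26% of those tested, which sets no bound, because autosomal genes can differ by sex as well. Age, which the design names, stays open beside sex as an untested cause of each of the other day differences. Xist and Ddx3y, also of the sex-linked list, were not measured.

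Across all genes the differences between injections at day 7 and day 30 were not correlated. The fatty acid oxidation list was higher on both days, while 3 lists were outside the matched range in opposite directions. The correlation of -0.0384 raised the question of an equal Tbx6 effect over many genes, so it is no separate test of it. Across genes the differences had a standard deviation of 0.47 at day 7 and 0.40 at day 30, beside which a small shared effect would hardly show. The correlation speaks only against an effect large beside that spread. Among genes at or above the 75th percentile of expression it was -0.0267, so dim probe sets did not hide such a large effect either. A small shared effect, an effect on few genes, or one that differs with age remains possible. Genetic differences between outbred mice over long stretches of chromosome would make neighbouring genes differ together, but neighbours correlated by 0.0083 at day 7 (highest of the shuffles of gene order 0.0356) and 0.0235 at day 30 (highest 0.0277). The same measure came to 0.0556 for the day difference after PBS, above its shuffles (0.0296) but by less than the margin of 0.05 set beforehand, so the test had little reach and speaks only against a strong pattern of this kind. Single variable loci, such as that of Cwc22, and differences between the hearts sampled stay open.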

How the results depend on the processing

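Leaving out X and Y genes, leaving out lung, airway and fat genes, and keeping genes above background on all 4 arrays were alternatives chosen after the result was seen; the others were planned. The count of 0 genes for injection held under all 6 alternatives of the limma test, with 19 to 869 genes at an unadjusted p under 0.05. The count for day ranged from 1815 to 2809. Quantile normalisation, centring and averaging of probe sets left all gene counts within 1.5 times of the reported ones. Other filters and the 2-fold rule moved counts by construction, since they change how many genes can be counted. Without a filter 3101 and 2918 genes differed between injections at day 7 and day 30, and 6590 between days after Tbx6. With a filter at the 75th percentile these became 603, 432 and 2258, with 2292 between days after PBS. At 2-fold they were 276, 209 and 2113, with 2002 after PBS. Genes with the same and with opposite directions on both days numbered 294 and 349 without a filter, 50 and 41 at the 75th percentile, 5 and 11 at 2-fold, and 91 and 91 among genes above background on all 4 arrays, so which was larger depended on the filter. The correlation of the day differences was 0.671 without a filter. Lists outside the matched range numbered 50 of 148 list and difference pairs, and 51 to 59 under the alternatives; 181 such list results held and 19 came inside the range. For the genes named, 365 values moved little and 29 moved more. Part of this was fixed by construction. Centring shifts all genes of an array equally, and the array medians hardly differed. Averaging can change only the few genes with more than 1 probe set. The count of values that moved little is therefore no measure of how firm the named genes are. The reading without the PBS array of day 7 cannot be had for day 7 or for the limma test, which it leaves with no residual degree of freedom; the day 30 difference and the Tbx6 day difference do not use it. Leaving out a day or an injection leaves a single pair of arrays, a value without a test. Probe sets near the background, such as that of Tbx6, limit what low genes can show. Beyond the day term of the additive model, no paired analysis was possible because each group has 1 array and the labels give no pairing.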

Other observations

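The list of this part was written before the single values of its genes were looked at but after medians of lists that hold some of them had been seen, and the list without fatty acid oxidation genes was chosen after the result was seen.

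The hypothesis came from genes that were higher after Tbx6 on both days, such as Fbp2 (1.21 and 0.93), from Klf15, whose day 7 readings were at background, and from the fatty acid oxidation list. The Tbx6 hearts may have come from animals with a stronger fasting or glucocorticoid response. Of 11 genes of that response already seen, 7 were at least 1.5-fold higher and 2 lower at day 7, Cebpd (-0.72) and Depp1 (-1.17). At day 30, 9 were higher and 0 lower. Having been seen, these 11 are no test. A list of 24 other genes of that response had a median difference of 0.19 at day 7 (percentile 98.6 of matched random lists) and 0.20 at day 30 (percentile 98.9), past the bound set beforehand on both days. The members did not move as a block. At day 7, 5 were at least 1.5-fold higher and 5 lower, with the glucocorticoid-induced gene Sgk1 at -1.20 and Per1 at -1.19. At day 30, 5 were higher and 0 lower, with Sgk1 at 1.09 and Txnip at 0.99. Of those counted as higher, Gadd45b at day 7 and Foxo3 at day 30 were compared with readings at background. The classical target Fkbp5 differed by 0.49 and 0.09. Of the 24 genes 4 also belong to the fatty acid oxidation list, whose medians had been seen, and Per1, Cdkn1a and Ccng2 belong to other lists fixed beforehand. Without the former 4 the remaining 20 had medians of 0.23 (percentile 99.1) and 0.14 (percentile 92.8), the latter inside the range. The feeding state, handling and hour of collection were not analysed here, and an effect of the vector or of Tbx6 on these genes is equally open.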
